A study of Arabidopsis thaliana with 12 samples.

How the data were processed

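The data are 12 arrays of total RNA from Arabidopsis thaliana Columbia-0, 6 from plants at normal iron and 6 from plants at high iron, assigned by the source names in the labels, with replicate numbers 1 to 6 taken from the sample titles. The authors deposited 1 intensity per probe and array on a linear scale, between 0 and 100. How these intensities were scanned, corrected for background and scaled is not given in the sources used here, so the unit and any centring stay unknown, and the direction of every change is that of the labelled groups. The 12 column medians ranged from 0.352 to 0.446 in high iron samples and from 0.555 to 0.618 in control samples, and the column means from 0.978 to 1.04. Between 123 and 145 values per column were 0, except in high iron samples 3 and 4 with 278 and 271. Between 1 and 4 values per column lay at the upper limit, where only a bound is known, and 1 probe did on all 12 arrays. At 0 on all 12 arrays were 46 probes.

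Genes were named from the platform annotation supplied with the series, which can be old, and symbols were updated through gene numbers with a table of assembly TAIR10.1, which held 690 of 692. Of 3439 probes, 692 had 1 gene, 870 had several and 1877 had none. All probes were tested, and only those with 1 gene were named. The 692 probes stand for 691 genes, and a gene with several probes was represented in lists by the brightest. No positions are given because the sources name no genome build.

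The design, the alternatives, the lists and the rule for named genes were set before the data were examined. Because the column medians differed by more than 10 percent (largest over smallest 1.76), arrays were quantile normalized. Values were then floored at the 5th percentile of the positive values (0.106) and taken to log2, which understates changes of dim probes. At this lowest level on all 12 arrays were 145 probes. Changes were tested two-sided per probe with limma 3.58.1 (lmFit and eBayes with a mean trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. The design called for averaging sets of samples whose deviations correlate above 0.7 inside every set. The sets 1 with 2, 3 with 4 and 5 with 6 had correlations from 0.56, so the rule was not met and the 12 samples were kept as replicates. The 6 averages, and the set as a random block (duplicateCorrelation with statmod 1.5.0, correlation 0.774), were fixed beforehand as alternatives.

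Samples with the same number in both groups deviated together, with correlations of 0.52, 0.51, 0.21, 0.13, 0.52 and 0.51 for the numbers 1 to 6, all above 0.1, and 12 of 12 samples correlated best with their own number in the other group. The numbers therefore pair the samples, a pairing that comes from the data and not from the labels. The fit of the 12 samples stayed unpaired, as fixed beforehand, and the replicate number entered as a block in an alternative fit. Samples of the same set but another number correlated between 0.11 and 0.49 across groups, so the pairing is mostly one of sets.

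The genes named were the 10 largest rises and the 10 largest falls in log2 change among single-gene probes that passed, up to 3 members of each list with the smallest adjusted p, and the ferritins FER1 to FER4, FSD1, CSD2, APX1 and IRT1 where measured, which gave 31 genes. None of the last 8 had a single-gene probe. The 19 lists covered photosystem I, photosystem II, electron transport and ATP synthase, the Calvin cycle, iron uptake and storage, plastid iron-sulphur clusters, antioxidant enzymes, chlorophyll and haem synthesis, plastid ribosomal proteins, plastid chaperones and proteases, isoprenoids, starch, oxylipins, sulphate assimilation and glutathione, nitrogen assimilation, senescence, root- and seed-preferential genes and common reference genes. Of these, 7 had a measured single-gene member and are described, and 12 had 0 and were not analysed here. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry; only plastid ribosomal proteins reached that size. Another 5 lists were written from the names of measured genes after the annotation was seen and before their changes were computed. They were the photosynthesis genes of the preset lists in 1 list, and thylakoid NDH subunits and photosystem assembly factors. The rest were thiol redox and antioxidant proteins, pentatricopeptide repeat proteins, and floral and reproductive regulators.

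The test was checked on simulated arrays of 3439 probes with the sets of samples built in and 200 probes changed, over 5 runs of the comparison of high iron with control. The 12 samples as replicates recovered 88.6% of 2-fold and 99.0% of 4-fold changes, with 48.6% of calls false. The set as a random block recovered 68.0% and 97.2% with 18.8% false, and the 6 averages recovered 43.4% and 88.8% with 6.05% false. In a second simulation, added after the data were seen, 48.0% of the variance between sets was shared by the sets of the same numbers in both groups, as estimated from these arrays. There 21.5% of calls over 12 samples were false, 38.7% with the replicate number as a block, 4.19% with the set as a random block, 1.87% over the 6 averages and 4.55% over the averages with the block. The number of arrays limits the precision of every value.

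Alternatives were median scaling, deposited values, no floor or a floor at the 10th percentile, leaving out the dimmest 25 percent of probes, eBayes without a trend or with robust variances, the replicate number as a block, array weights, stricter thresholds and leaving out each sample. Added after the data were seen were fits without high iron samples 3 and 4, without 1 set, with averages after median scaling or with a block, and with a running median over 25 neighbouring probe numbers removed from each array.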

Results

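Transcript levels were measured on single-value expression arrays in plants of Arabidopsis thaliana, ecotype Columbia-0, the common laboratory wild type of this small flowering plant. The labels describe 6 samples of total RNA from plants grown at normal iron (control) and 6 from plants grown at high iron, a condition the labels call oxidative stress. Each sample gave 1 intensity for each of 3439 probes, on a scale from 0 to an upper limit of 100. The tissue, the iron dose and the duration are not given in the sources used here. The comparison asks which transcripts differ between plants grown with excess iron and plants grown with normal iron.

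Among genes with a probe of their own, the transcript of AT4G35660 fell most at high iron, to 0.152 times the control level (log2 change -2.72, SE 0.12, n = 6 per group). The strongest rise with quantile normalization was that of CSLA01 (AT4G16590), at 3.56 times the control level (log2 change 1.83, SE 0.14). CSLA01 was among the dimmest 25 percent of probes. Its control mean was -2.69 on the log2 scale, near the floor of -3.24, although no value lay at the floor. CSLA01 is a cellulose synthase-like gene of the family that makes mannan. Rises also included CBL (AT3G57050), the cystathionine beta-lyase of methionine synthesis, at 1.22 on the log2 scale (SE 0.24), and APS4 (AT5G43780), an ATP sulfurylase of sulphate assimilation, at 1.12 (SE 0.15). Falls included AT3G18870, a gene of the mitochondrial transcription termination factor family, at -1.23 (SE 0.09), and AT5G39980, which codes for a pentatricopeptide repeat protein, at -1.15 (SE 0.25). These 6 genes passed in limma with all 12 samples counted as replicates, with adjusted p from 1.02e-07 to 0.00438. Each moved the same way in all 3 sets of samples described next, which is in part built in, as they were chosen over the same samples. Over averages of these sets the SE was 0.20 for CSLA01 and 0.34 for CBL. There CBL (adjusted p = 0.113), AT5G39980 (0.126) and APS4 (0.0616) did not pass. With the replicate number as a block over these averages, all 6 genes did not pass (adjusted p from 0.0664 to 0.0915). With deposited values CBL stood at 0.62 and APS4 at 0.55. AT4G17070 rose more than CSLA01 with median scaling (2.44 against 1.74) and with deposited values (1.92 against 1.22).

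Within each group the 6 samples fell into 3 sets by their numbers, 1 with 2, 3 with 4 and 5 with 6. Deviations from the group mean correlated between 0.56 and 0.82 inside a set and between -0.70 and -0.25 across sets, over probes, which are not independent replicates. The labels do not say what a number marks, and they do not name separate plants, so p-values measure only the spread between these samples, which may be technical. If the samples of a set are repeat measurements, the number of replicates is 3 per group and p-values over 6 per group are too small. Counts and calls are therefore given both over 12 samples and over the 6 averages of the sets. Each SE is that over 12 samples unless stated, which counts the samples of a set as independent. Over the averages the SE is larger for the 31 named genes.

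**Figure D1:**
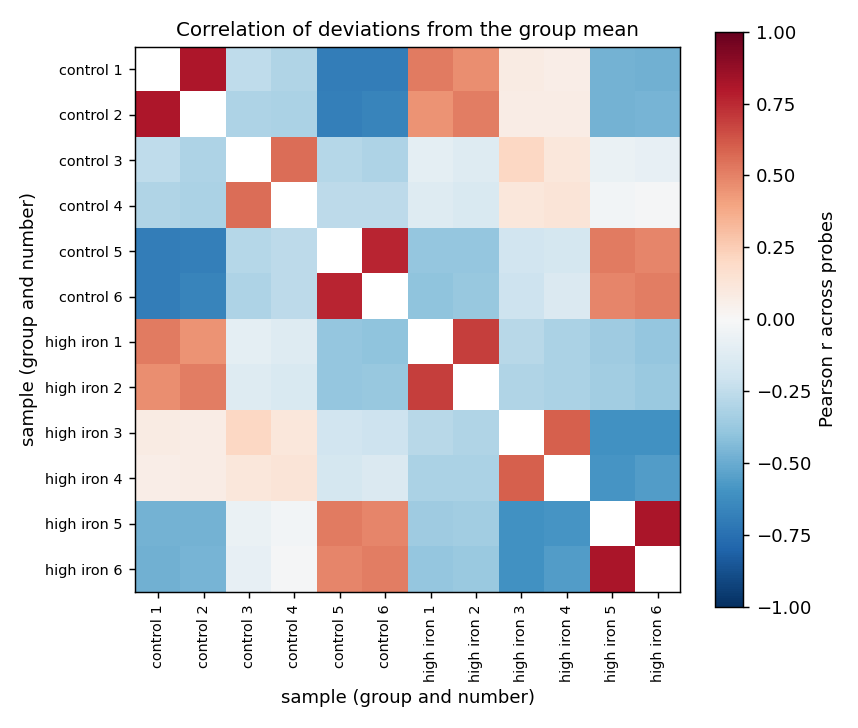
Pearson correlation, across all 3439 probes, between samples' deviations from their group mean on the log2 scale; both axes list the 12 samples by group and number, and the colour runs from -1 (blue) to 1 (red). Inside the sets 1 with 2, 3 with 4 and 5 with 6 the values lie between 0.56 and 0.82, and across sets of 1 group between -0.70 and -0.25.

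Over the 12 samples, 1149 of 3439 probes differed at an adjusted p under 0.05, of which 625 were higher and 524 lower at high iron. On simulated arrays with such sets and 200 of 3439 probes changed, 48.6% of the calls over 12 samples were false, against 6.05% over 6 averages. With set deviations partly shared across the groups, as in these samples, 21.5% and 1.87% were false. These shares depend on the number of changed probes and the size of their changes, which are unknown for the real arrays. They are therefore not the false shares of the real calls. Probes of a single named gene made up 246 of the 1149, 136 higher and 110 lower. Over the 6 averages, 82 probes passed, 45 higher and 37 lower, and 81 of them were also among the 1149 with the same sign. Of the 82, 18 belonged to a single named gene, 11 higher and 7 lower. With the set as a random block 491 probes passed, 283 higher and 208 lower. With the replicate numbers as a block over the 6 averages, 1 probe passed, with a lower value, and AT4G35660 did not (adjusted p = 0.0664). The count over averages rests on every set: with the normalization of all 12 samples kept, it was 19, 2 and 5 without control set 1, 2 or 3, and 7, 36 and 16 without high iron set 1, 2 or 3.

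The split of the calls depends on how the arrays are scaled, because the arrays of the 2 groups differed in their spread of intensities. The median intensity was 0.580 ± 0.030 (SD, n = 6) in control and 0.405 ± 0.043 in high iron samples, and the groups did not overlap (two-sided exact permutation p = 0.0022 over 12 samples and 0.10 over 6 averages, each the smallest possible). The brightest 10 percent of probes lay 1.78 ± 0.08 log2 units above the median of all probes in control samples and 2.55 ± 0.21 above it in high iron samples (SD, n = 6). Quantile normalization, used for all values unless another scaling is named, removes this difference. With median scaling the calls were 850 higher and 436 lower (66.1% higher, against 54.4% with quantile normalization). With the values as deposited they were 291 higher and 1601 lower (15.4% higher), with a median change of all probes of -0.40. Of the 1149 probes, 139 had the other sign with deposited values and 46 after median scaling. Of these, 9 and 18 also passed with the other sign.

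**Figure D2:**
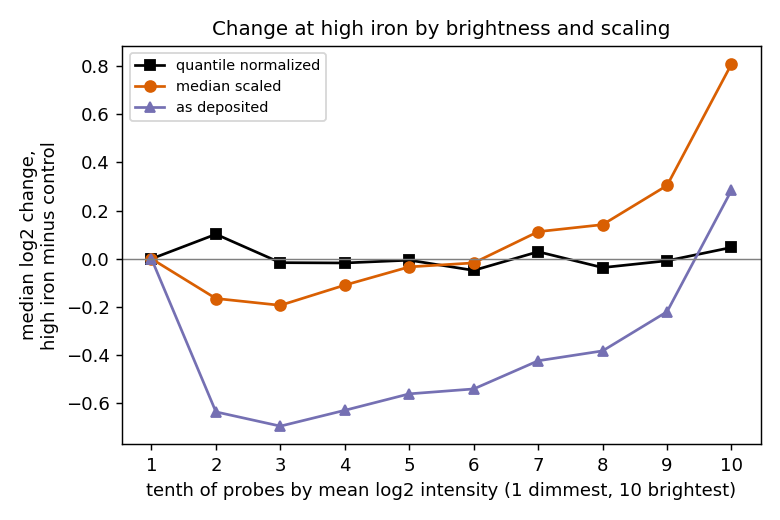
Median log2 change (high iron minus control, vertical axis) of the probes in each of 10 bins of mean log2 intensity (horizontal axis, from 1, the dimmest, to 10, the brightest), under quantile normalization, median scaling and with values as deposited. After median scaling the bins run from -0.19 to 0.81, and with deposited values from -0.69 to 0.28, while quantile normalization leaves them between -0.05 and 0.10.

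Among the 10 largest rises, AT4G17070 rose by 1.48 (SE 0.15) on the log2 scale, AT2G06040 rose 2.47-fold (log2 SE 0.17) and AT4G22490 by 1.25 (SE 0.15). AT2G37510, AT1G76220, AT1G51350, AT1G35510 and APS4 rose by 1.12 to 1.18. CSLA01, CBL, AT2G06040 and AT4G22490 lay in the dimmest 25 percent of probes, as did AT5G48130 among the falls. The fit without those probes held 24 of the 31 named genes and did not test these. Among the 10 largest falls, AT5G38750 changed by -1.55 (SE 0.38), AT1G19490 by -1.51 (SE 0.29), AT5G11550 by -1.31 (SE 0.28) and AT2G36480 by -1.28 (SE 0.15). AT5G40470 changed by -1.10 (SE 0.21), and AT5G48130 by -1.11 (SE 0.30), with -0.35, -2.13 and -0.84 in the sets 1 to 3. In AT5G48130 and AT5G38750, 2 of the 6 high iron values lay at the lowest level, so the size of their change depends on the floor. Without a floor AT5G48130 stood at -2.73 and did not pass (adjusted p = 0.0797), and without high iron samples 3 and 4 it stood at -0.62. AT5G38750 stood at -0.97 without a floor, but its high iron samples 1 and 2, deposited as 0, counted as missing there. That smaller value therefore leaves out its 2 lowest samples. The remaining fall was that of AT3G52960, a peroxiredoxin of plastids that removes peroxides, at -1.48 (SE 0.52, adjusted p = 0.0462); its change was -0.21, -2.91 and -1.33 in the sets 1 to 3, the 4 probes with the nearest numbers had a median change of -1.55, and its adjusted p was 0.131 with the set as a random block and 0.0591 after median scaling. Without a floor it stood at -2.32 (adjusted p = 0.110) and with array weights at -0.58 (0.231), whereas with a running median over neighbouring probe numbers removed it passed at -1.38 (0.0427). Its call ended in 9 of 12 fits that left out 1 sample, and its change was -0.68 without high iron samples 3 and 4 (adjusted p = 0.106). All 20 genes kept their sign in all 3 sets and under all 3 scalings, but 6 sizes moved by over 1.5 times. The shared sign is in part built in, because the 20 were chosen as the largest changes over these same samples. With deposited values CSLA01 stood at 1.22, AT2G06040 at 0.63, CBL at 0.62, APS4 at 0.55 and AT4G22490 at 0.54, and after median scaling AT4G17070 stood at 2.44. Over the 6 averages 4 of the 20 passed: AT4G35660 (adjusted p = 0.00575), AT3G18870 (0.0266), CSLA01 (0.0310) and AT4G17070 (0.0463). With the replicate number as a block over the averages these 4 did not pass (adjusted p from 0.0664 to 0.0730), nor did the others of the 20. With 1 average left out in turn, AT4G35660 passed in all 6 fits and CSLA01 in 2 (adjusted p from 0.0183 to 0.143). AT3G18870 and AT4G17070 passed in 0, with adjusted p from 0.0552 to 0.115 and from 0.0712 to 0.168. Without samples 3 and 4 of both groups, all 10 rises passed and 7 of the 10 falls did not, namely AT5G38750, AT1G19490, AT3G52960, AT5G11550, AT5G39980, AT5G48130 and AT5G40470, with adjusted p from 0.0512 to 0.189. In that fit AT5G11550 stood at -0.85, AT3G52960 at -0.73 and AT5G48130 at -0.56. Without samples 5 and 6 of both groups AT3G52960 and AT5G48130 did not pass, and without samples 1 and 2 all 20 passed, with AT3G52960 at -2.23. With the set as a random block 17 of the 20 passed, the exceptions being AT3G52960, AT5G11550 (adjusted p = 0.0525) and AT5G48130 (0.106).

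**Figure D3:**
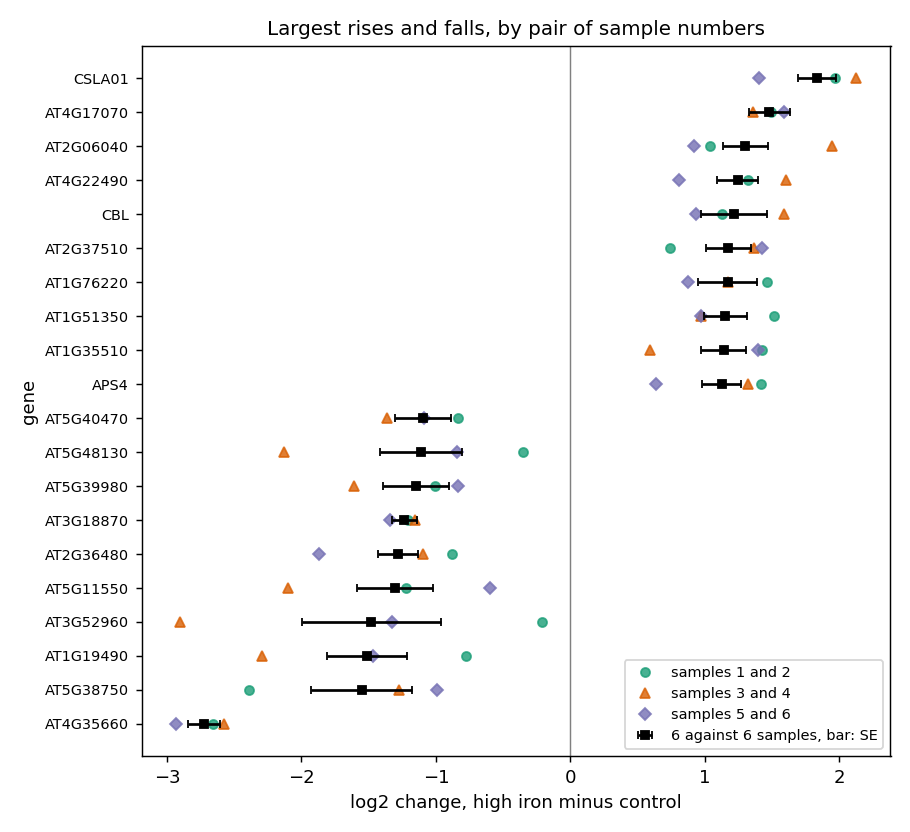
Log2 change (high iron minus control, horizontal axis) of the 10 largest rises and 10 largest falls among probes of a single named gene that passed over 12 samples; black squares with bars give the estimate and its SE for 6 against 6 samples, and coloured points the change inside each set. AT4G35660 lies between -2.57 and -2.93 in the 3 sets, whereas AT3G52960 ranges from -0.21 to -2.91.

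Of 6 measured members of the lists for the photosystems and the Calvin cycle, 1 rose, 0 fell and 5 did not pass after quantile normalization. The one that rose was SBPASE (AT3G55800), the sedoheptulose-bisphosphatase of the Calvin cycle, at 0.48 (SE 0.09, adjusted p = 0.00249), with 1 of the 2 measured Calvin cycle genes passing when adjusted over the list alone. It did not pass over the 6 averages (adjusted p = 0.132) or with deposited values, where it stood at 0.09. PRK, the phosphoribulokinase of the same cycle, had a value of 0.18 (SE 0.21). The photosystem I subunit PSAN (-0.08, SE 0.08), the photosystem II subunits PSBW (0.19, SE 0.09) and PSBY (0.20, SE 0.14) and the antenna gene LHB1B2 (0.00, SE 0.08), which has near-identical copies that may share its probe, did not pass. For photosystem I and II 0 of 1 and 0 of 3 genes passed when adjusted over the list alone. PSBW passed with the replicate number as a block (adjusted p = 0.0105) and with array weights (0.0461), but not over the averages with that block (0.228) or without it (0.465), nor with the set as a random block (0.269). Without samples 1 and 2 of both groups PSAN passed at -0.24 (adjusted p = 0.0413), and without samples 5 and 6 PSBW passed at 0.16 (0.0392) and PSBY at 0.39 (0.0343). The values of this group depend on the scaling of the arrays. After median scaling PSBW stood at 1.34, LHB1B2 at 0.88 and PSAN at 0.84, and 4 of the 6 rose. These 3 genes also passed over the 6 averages after median scaling, with adjusted p of 0.0452, 0.0290 and 0.0396. With deposited values they passed at 0.82, 0.35 and 0.32 (adjusted p = 0.000395, 0.00597 and 0.00165). All 3 are bright, and the brightest 10 percent of probes had a median change of 0.81 after median scaling and 0.28 with deposited values. As 1 list, formed after the annotation was seen, the 6 genes had an adjusted p of 0.433 in camera after quantile normalization (0.651 with an estimated correlation). After median scaling the adjusted p was 0.0116, against an adjusted p of 0.642 with an estimated correlation. In fry, which tests for a common direction and does not compare the list with other genes, the adjusted p was 0.0433 over 12 samples and 0.000143 after median scaling, but 0.259 over the 6 averages.

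Of 6 measured genes of plastid ribosomal proteins 1 rose, 1 fell and 4 did not pass over 12 samples, and 2 passed when adjusted over the list alone; over the 6 averages 0 of the 6 passed. AT1G64510, a small-subunit protein, rose by 0.72 (SE 0.10, adjusted p = 0.000269), AT1G29070, a large-subunit protein, changed by -0.75 (SE 0.26, adjusted p = 0.0458), and AT4G01310 had a value of -0.18 (SE 0.14) but passed with deposited values, at -0.60. AT1G64510 and AT1G29070 did not pass over the 6 averages (adjusted p = 0.0611 and 0.258). With deposited values AT1G64510 did not pass, at 0.14. In AT1G29070 2 of the 6 high iron values, in samples 3 and 4, lay at the lowest level, and without a floor it stood at -2.37 and did not pass (adjusted p = 0.116). It stood at -1.15 with deposited values and at -0.48 with array weights. AT1G29070 did not pass with the set as a random block (0.231), after leaving out 1 sample in 10 of 12 fits, or without high iron samples 3 and 4 (-0.33, adjusted p = 0.0771). The list's median change was -0.15 (camera p = 0.720, and p = 0.721 with an estimated correlation), and fry gave p = 0.464 for a common direction and 0.00031 for changes in either direction. AT5G65220, a member, was at the lowest level on all 12 arrays.

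The other lists had few measured genes. Of the 2 antioxidant genes, AT3G52960 fell, and CCS (AT1G12520), the copper chaperone of superoxide dismutase, had a value of 0.48 (SE 0.34, adjusted p = 0.315). CCS passed with the replicate number as a block (adjusted p = 0.00525) and, at 0.86, with array weights (0.0231), but not over the averages with that block (0.0876) or without it (0.591), nor with the set as a random block (0.542), and its value was -0.21 with deposited values. Of these 2 genes 1 passed when adjusted over the list alone. CHLM, the magnesium-protoporphyrin methyltransferase of chlorophyll synthesis, was the 1 measured gene of its list and changed by -0.48 (SE 0.10, adjusted p = 0.0049), a call that ended over the averages (0.0931), with the set as a random block (0.192), after median scaling (-0.32, 0.0714) and without samples 5 and 6 of both groups (0.0666); with deposited values it stood at -0.84. APS4 was the 1 measured gene of sulphate assimilation and glutathione; over the 6 averages its adjusted p was 0.0616. Each of these lists of 1 gene had 1 gene passing when adjusted over the list alone. No probe of a single named gene stood for a ferritin or for any other of the 35 genes of iron uptake, transport and storage, so these were not analysed here.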

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

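The tests of the sets of samples, of photosynthesis genes against brightness and of the neighbours of AT3G52960, and the splits that keep sets whole, were chosen only after the results were seen; the counts over other splits, the gap between groups in brightness and the test of neighbouring probe numbers were written down first.

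In AT1G64510, the plastid ribosomal protein gene that rose, control sample 6 lay apart from the other 5 control samples, at -2.09 on the log2 scale, with a gap of 0.670 of the group's range. Of 72 groups of values examined 1 stood out in this way, and chance alone would give about 1 in 20.

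The samples of each group fall into 3 sets by number, with correlations of deviations from 0.560 upward inside sets and at most -0.254 between sets of a group. Repeat measurements of 3 RNA samples, or a batch shared inside each set, may account for this, as both need values above 0 inside and at or below 0 between sets. Values between sets lie below 0 in part by construction, because deviations from a group mean sum to 0. Samples of the same set also deviate together across the 2 groups, which repeat measurement of 1 RNA sample would not give and a shared batch would. No biological explanation was tested, since the labels name none.

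At high iron the bright probes stood higher above the rest: the lowest high iron sample exceeded the highest control sample by 0.527 log2 units in this measure, against a range of 0.444 inside a group. A gap above that range was set beforehand as the sign that chance differences between arrays in scaling or background are not the cause, but that bound took the 12 arrays as independent; with 3 sets per group full separation happens in 1 of the 10 splits of the averages by chance, so after the value was known this was left open. A candidate explanation is a rise of photosynthesis genes, of which the 6 measured lie between the brightness percentiles 62.1 and 99.7, and their median change after median scaling, 0.73, lay at percentile 68.2 of 10000 lists matched on brightness. A percentile of at most 95 was first to count against it, but only 15.8% of the matched probes have 1 named gene and the others may be photosynthesis genes as well, so this too was left open after the value was known. Scanning or labelling that differed with the group and a true change in the abundance of many transcripts cannot be told apart here, as 1 value per probe is all that was used.

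Probes with neighbouring numbers changed together: the correlation of log2 changes between 2558 pairs of neighbours was 0.195, and the highest of 1000 shuffles was 0.069. A place effect on the array may be a cause. Differences between sets of the same group hold no difference between iron levels, and had a median neighbour correlation of 0.237. It ran from 0.11 to 0.18 in control and from 0.30 to 0.52 in high iron samples. The high iron sets may differ in their response to iron, and neighbouring probes may hold related genes. The test therefore cannot single out a place effect. The fall of AT3G52960 is a case in point: its 4 nearest probes had a median change of -1.55, at percentile 0.05 of 2000 windows, and 3 of them changed by -1.77 to -2.97 in sets 2 and 3 but by -0.09 to -0.72 in set 1. A local array defect in the high iron samples may give these shared falls, and a true fall of this peroxiredoxin gene was not excluded. With a running median over 25 probe numbers removed AT3G52960 stayed at -1.38 (adjusted p = 0.0427). That span is wider than these 4 probes and would leave a local dip as well as a true fall, so it cannot tell them apart. Whether probe numbers follow places on the array is not given in the sources used here.

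In 1 of 100 splits of the 12 samples into 6 and 6, the real one, 1149 or more probes passed, and the highest count of another split was 1, but nearly all of these splits divide sets, whose samples are not independent, so the bound of 5 in 100 set beforehand was wrong for these samples. The splits that keep every set whole number 10, too few for a share under 0.05; among them the real one gave 1149 probes and the highest other 666, so that count does not exclude chance. Of these 10, 4 part all 3 pairs of sets with the same numbers, as the real split does, and the highest of the others among them gave 0. A first rank among 4 splits is too weak to exclude chance either. Over the 6 averages, 1 of 10 splits, the real one, gave 82 probes, and the highest other gave 1; 10 splits are too few for a share under 0.05. For the plastid ribosomal protein list 57 of 100 splits gave a camera p as small as the real 0.720, so chance is not excluded; the smallest p of another split was 0.0989.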

How the results depend on the processing

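Fits without high iron samples 3 and 4, without 1 set, with averages after another scaling or with a block, and with the running median removed were chosen only after results were seen. The number of probes that passed, 1149, stayed within 1.5 times under median scaling, other floors, filters and variance models, array weights, with the running median removed (1222) and without high iron samples 3 and 4 (1068), and without 1 set of both groups (825 to 1121, although 7 of the 10 largest falls ended without set 2), and leaving out 1 sample gave 999 to 1169. It was 82 over averages, 491 with the set as a random block, 1892 with deposited values, 172 with at least a 2-fold change and 720 at an adjusted p under 0.01. Averages gave 259 after median scaling, 33 without high iron samples 3 and 4 when the other arrays were normalized again (36 when not), and 311 with the running median removed, of which 72 were among the 82; the random block after median scaling gave 690. A stricter threshold gives fewer calls by construction; the cause of the other moves was not tested. From 12 samples to averages, calls on simulated arrays fell from 365.6 to 140.8, or from 238 to 138.4 with set deviations shared across groups. Both falls are smaller than that seen here. The simulated changes were all 2-fold or 4-fold, whereas 172 of the 1149 real calls reached 2-fold. The falls can therefore not be compared directly.

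With the replicate number as a block 1392 probes passed; of the 31 named genes PSBW and CCS gained a call, which neither had as a block over averages, and none lost one, and it changed no list's call. As a block over averages it left 1. Of the 31 genes 20 lost a call over averages, 5 with the set as a random block and 3 without a floor (AT3G52960, AT5G48130 and AT1G29070), with their sign kept. The plastid ribosomal list kept its direction and did not pass in camera in any fit, with medians from -0.16 to -0.07 when 1 sample was left out. In fry for changes in either direction its p was 0.00031 over 12 samples, 0.000148 over averages and 0.00316 after median scaling. The list's median moved more in other fits. From -0.15 over 12 samples it went to -0.44 with deposited values and -0.039 after median scaling. It was -0.26 with the running median removed and -0.022 without set 3 of both groups. Without the dimmest probes too few members were left to test.

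Of the 1149 probes that passed, 139 had the other sign as deposited and 46 after median scaling (41 and 7 of the 246 with a single named gene). With that other sign 9 of the 139 and 18 of the 46 passed (1 of the 41 and 3 of the 7). Among the 31 genes named by the rule, and among the lists in camera, values that had not passed turned sign. Outside the rule, LPA19, AGL26, LAS and CCL had passed and turned sign with deposited values, as given below. CCL also turned sign after median scaling and passed there. PSAN was 0.84 after median scaling, also over averages or with the random block, and 0.32 as deposited, and LHB1B2 0.88 and 0.35. Both genes passed in each of these fits. LHB1B2 was 0.12 with array weights, from -0.0456 to 0.0455 when 1 sample was left out, 0.021 without high iron samples 3 and 4 and 0.031 without set 1. PRK was -0.21 as deposited, -0.040 without high iron samples 3 and 4 and -0.17 without set 2; CCS was -0.21 as deposited. The NDH list's median was -0.32 as deposited, -0.00495 without dim probes, -0.086 with array weights, -0.00697 with the running median removed and -0.00315 without set 3. The thiol redox list's was -0.21 and the floral list's -0.38 as deposited, and the floral list's -0.066 with the running median removed. As deposited the median of all probes was -0.40. Minus that median the NDH, thiol redox and floral lists stood at 0.085, 0.19 and 0.025, so they did not fall against the other probes there. The cause of the other turns was not tested. Signal over background is not given in the sources used here, so the weakest values cannot be called present.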

Other observations

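The 5 added lists and the genes called over averages were chosen only after the annotation or the results were seen.

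Of 17 measured genes of pentatricopeptide repeat proteins, which process RNA in plastids and mitochondria, 2 rose, 6 fell and 9 did not pass over 12 samples. AT5G39980 (-1.15, SE 0.25, and -0.71 with the running median removed) and AT2G17670 (-1.04, SE 0.18, and -1.66 with deposited values) fell most. AT4G21170 rose by 0.65 (SE 0.07), or 1.02 after median scaling, and was the 1 member that passed over the averages (adjusted p = 0.0463). The list's adjusted p in camera was 0.433, and 0.502 with an estimated correlation. In fry, which tests for a common direction and does not compare a list with other genes, its adjusted p was 0.0250 over 12 samples, a call that ended over the averages (0.259) and after median scaling (0.831). With median scaling 4 rose and 5 fell, and with deposited values 2 rose and 12 fell. Among 6 thiol redox and antioxidant proteins 2 rose and 1 fell. The rises were those of GLDH, the last enzyme of ascorbate synthesis, at 0.99 (SE 0.15), and CHL, the plastid lipocalin, at 0.95 (SE 0.31). The peroxiredoxin AT3G52960 changed by -1.48. The plastid thioredoxin reductase NTRC (0.23, SE 0.15) and sulfiredoxin SRX (-0.14, SE 0.14) did not pass, and the list's adjusted p in camera was 0.433 (0.651 with an estimated correlation). With median scaling 2 rose and 0 fell, and with deposited values 1 rose and 2 fell. GLDH stood at 0.43 and CHL at 0.37 with deposited values, where CHL did not pass (adjusted p = 0.298), nor did it with the set as a random block (0.0783).

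Among 8 thylakoid NDH subunits and photosystem assembly factors, LPA19 rose by 0.31 (SE 0.08) and PSB27, an assembly factor of photosystem II, changed by -0.86 (SE 0.14), while 6 did not pass, among them CCB3, which was at the lowest level on all 12 arrays; the list's adjusted p was 0.932 (0.959 with an estimated correlation). With median scaling 2 rose and 1 fell, and with deposited values 1 rose and 4 fell. LPA19 turned to -0.06 with deposited values and did not pass there (adjusted p = 0.546) or with the set as a random block (0.116), and PSB27 stood at -0.41 after median scaling. The list of floral and reproductive regulators was written from gene names, which do not show that each member has that role. Of its 6 genes 3 rose and 0 fell with quantile normalization. These were AGL103 at 0.62 (SE 0.11), AGL26 at 0.44 (SE 0.10) and LAS at 0.19 (SE 0.06). With deposited values 0 rose and 3 others fell, SPL (-0.65), SAP (-0.72) and AGL54 (-0.66). There AGL103 stood at 0.20, AGL26 at -0.01 and LAS at -0.10, and these 3 did not pass; with the set as a random block AGL26 (adjusted p = 0.144) and LAS (0.216) did not pass either. After median scaling LAS stood at 0.42. The floral list's adjusted p was 0.433 (0.502 with an estimated correlation). In fry the floral list's adjusted p for a common direction was 0.000487 over 12 samples and 9.21e-05 after median scaling, and 0.0549 over the averages, where the call ended. The thiol redox list's was 0.0543, 0.0618 and 0.259 in these fits and the NDH list's 0.906, 0.0618 and 0.888. Of the thiol redox, NDH and floral lists 0 members passed over the averages.

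Besides the genes named by the rule, 14 single-gene probes passed over the averages, chosen here after their values were seen. Among them AT4G37230 rose 2.18-fold (log2 change 0.39 with deposited values) and AT2G28660 2.15-fold, and on the log2 scale AT1G03660 changed by -1.03 and AT1G17744 by -0.86. CCL changed by -0.39 over 12 samples (adjusted p = 5.42e-05) but stood at 0.62 after median scaling, where it passed in the other direction (0.00513). Over averages after median scaling it did not pass (0.126), nor did it with deposited values, at 0.10 (0.345). Of the 18 single-gene probes that passed over averages, 15 passed with the same sign with the running median removed as well.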
